A study of Mus musculus with 15 samples.

How the data were processed

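Drop-seq, which captures polyadenylated RNA of single cells on barcoded beads, was run on whole hearts of E14.5 mouse embryos of the C57BL6/N background. The libraries comprise 7 from Adamts19 wild-type (WT) and 8 from homozygous knockout (KO) embryos. KO replicates 1 to 4 carry the allele labelled tm4a (litter 5 for replicate 1, litter 6 for replicates 2 to 4), and KO replicates 5 to 8 the allele labelled tm4b (litter 7). WT replicates 1 and 2 come from litter 1, 3 and 4 from litter 2, 5 from litter 3, and 6 and 7 from litter 4. The description of WT replicate 4 carries the replicate number 3, as does that of WT replicate 3, while the titles and the columns of the deposited table number them 4 and 3, and the titles were used. Per the labels, the 8 KO libraries and WT replicate 5 share a flow cell, and the other 6 WT libraries were sequenced on other flow cells. No litter holds both genotypes and no litter holds both alleles. How many embryos a library holds and which part of Adamts19 is deleted are not given in the sources used here.

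The deposited values are UMI counts per gene and barcode, whole numbers that are not normalized. Per the submitters' processing notes, bcl2fastq 2.17, Seurat 2.1 and the mm10 build were used; the role of each tool is not given in the sources used here. In the deposited table every library's shallowest barcode has 251 detected genes and the highest mitochondrially encoded share per library lies between 9.84% and 10.0% of UMIs, so barcodes had been filtered before deposit. The table holds 55152 barcodes and 16809 genes, and 0 columns belonged to no sample. A feature named LacZ is counted alongside the mouse genes. Sequencing is from the 3′ end of transcripts, so a tag outside the deleted part of Adamts19 says nothing about that part.

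Cells with at least 300 detected genes and at most 30% mitochondrially encoded UMIs were kept (the latter limit removed nothing). Scrublet as implemented in scanpy 1.11.5 was run per library, and its called doublets were removed. It marked 279 of 50899 cells (0.548%), and under 0.5% of cells in 12 of 15 libraries, so doublets were for the most part not recognised. For that reason the removal of the 5% of cells with the highest doublet score in each library was added as an alternative. The 50620 kept cells were scaled to 10000 UMIs each, log transformed, and clustered on 2000 variable genes chosen per library without Adamts19, sex-linked and mitochondrially encoded genes. The clustering used 30 principal components, 20 neighbours and the Leiden algorithm at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9), and gave 26 clusters.

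A cluster was called "X-like" from 15 marker lists (cardiomyocyte, valve interstitial, fibroblast, epicardial, mural, endocardial, vascular endothelial, lymphatic endothelial, valve endothelial, erythroid, macrophage, other leukocyte or platelet, neural crest with glia and neurons, epithelial, hepatocyte). Leading genes were ranked by fold over the other cells after adding 20 CPM, among genes seen in at least 5% of the cluster's cells. A cluster took the class whose markers had the highest mean log2 fold, or the class with most markers among the top 10 leading genes if these were at least 2 and more than those of the former class. At least 3 markers of the class had to be over 2-fold higher than in the other cells. In 1 fibroblast-like cluster at Leiden resolution 1.5 and 1 valve interstitial-like cluster with called doublets kept, the top 10 held 0 markers of the own class and 1 of another. The smaller, mitotic valve interstitial-like cluster held 1 of each and shared 4 of its top 10 genes (Fbln5, Eln, Sfrp2 and Rgs5) with the mural-like cluster, so its class is less certain. A cluster led by haemoglobin genes with a median haemoglobin share under 20% of UMIs stayed unnamed. It held 6.37% ± 5.53 of kept cells in WT and 2.45% ± 1.55 in KO libraries (mean ± SD, n = 7 and 8). That threshold was set after the clusters were seen. The trabecular-type cluster is a cardiomyocyte-like cluster led by Gtsf1, Cited1, Nppb, Nppa and Gja5.

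UMI counts were summed per library over all kept cells and over each class, leaving out libraries with under 10 cells of the class. Sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are log2 of KO over WT, or of tm4b over tm4a, with their standard error (SE), and n counts libraries. Levels of Adamts19 and LacZ are CPM of the library or class, from its own UMI total. Levels of the other genes are CPM over the tested genes of the sum, scaled by the TMM factors. Both are given as mean ± SD. Shares of 9 classes were compared by two-sided exact permutation tests of the difference in mean percent of kept cells, adjusted over the classes. Adamts19 in WT valve interstitial-like cells was set against all other cells by a two-sided exact sign-flip test on log2(CPM + 1). Intervals are exact binomial at 95% and floors are 3 counts over the group, and both cover counting error only. Thinned shares use cells thinned to 1000 UMIs. The tests in valve endothelial-like cells and of LacZ between alleles were added after the clusters and counts were seen.

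Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, in limma 3.58.1 on log2 CPM with a prior count of 2. The adjusted p-values are over the lists of a class with at least 3 tested members. The 23 lists are the ADAMTS family without Adamts19, genes near Adamts19, proteoglycans and hyaluronan matrix, collagens and collagen processing, basement membrane, elastic fibre, valve development transcription factors, shear stress response, Notch pathway, TGF-beta and BMP pathway, and Wnt pathway. They also include DNA replication, mitosis, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, immediate early and heat shock genes, interferon and MHC class I, calcium handling and conduction, haemoglobin, abundant cardiomyocyte transcripts, and sex-linked genes. The marker lists were tested in the same way.

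Adamts19 is always named. In each gene test the named genes are the 12 with the highest and the 12 with the lowest log2 fold change among those past the threshold, at an average log2 CPM of at least 5 and outside the sex-linked and haemoglobin lists. Members of a list past the threshold are added, up to 4 per list in order of adjusted p. Where fewer than 5 genes passed, the 5 with the smallest p in each direction are named as not passing. Klf2, Vcan, Sox9, Postn and Hapln1 are given in valve interstitial-like and endocardial-like cells whether or not they pass. This rule, the lists, the comparisons and the alternatives not said to be added later were fixed before the data were examined. Genes outside it are said to be chosen after their values were seen.

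Alternatives were DESeq2 1.42.0 (Wald test), RLE size factors, no filter on low counts, a replicate block, flow cell as a covariate, counts summed per litter, each library left out in turn, at least 500 genes per cell, called doublets kept, Leiden resolution 1.5 (31 clusters), haemoglobin genes or erythroid-like cells left out, and each allele alone against WT. After the data were seen, 2 more were added: the largest valve interstitial-like cluster alone, without the mitotic one, and leaving out WT replicates 1 to 4, because 45 genes separated them from WT replicates 5 to 7 over all cells. For shares they included the percent of kept cells that are not erythroid-like, and for Adamts19 by class a pseudocount of 10. With flow cell as a covariate the genotype effect rests on WT replicate 5 against the 8 KO libraries. For each gene test up to 100 splits of the libraries into groups of the same sizes were run. Other software was python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

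The gene test was tested on simulated counts with 200 changed genes. For KO against WT over all cells (13437 genes) it recovered 88 of 100 genes changed 2-fold and 95 of 100 changed 4-fold, and 4.69% of its calls were false. In valve interstitial-like cells (8593 genes) it recovered 78 and 87 of 100, in vascular endothelial-like cells (4106 genes) 75 and 83, and for tm4b against tm4a over all cells (13527 genes) 82 and 95. False calls there were 6.25%, 4.24% and 6.35% of the calls. Counts were drawn independently for each library and gene, without litter or flow cell effects, so these rates need not hold for the real libraries. The permutation test gave p under 0.05 in 8.3% of 60 simulated draws with no difference and in 100% of 20 draws with a difference of 3 SD. Within WT and within KO no 2 libraries were duplicates: the smallest chi-square per degree of freedom between libraries of a group was 5.47, for KO replicates 7 and 8. Pairs of a WT and a KO library were not compared. Raw reads were not analysed here.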

Results

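Single-cell transcriptomes of whole E14.5 mouse hearts were compared between 7 Adamts19 wild-type (WT) and 8 homozygous knockout (KO) libraries. The question, as the series title gives it, is what loss of this secreted metalloprotease does in a heart that later develops valve disease. WT replicates 1 to 7 held 8468851, 11340443, 10142912, 7728071, 6329008, 6961902 and 6215439 UMIs. KO replicates 1 to 8 held 9587553, 8553678, 5810774, 5477109, 10105950, 9982694, 9427692 and 7807243. Libraries had 2783 to 4914 barcodes, and 22308 WT and 28312 KO cells were kept. The median UMI count per kept cell was 1806 ± 327 in WT and 1540 ± 180 in KO libraries (mean ± SD, n = 7 and 8, exact permutation p = 0.0713). Clusters were named as cardiomyocyte-like (8 clusters), valve interstitial-like (2), fibroblast-like (3), endocardial-like (3) and vascular endothelial-like, valve endothelial-like, epicardial-like, mural-like, macrophage-like and erythroid-like (1 each), beside small epithelial, platelet and neuronal clusters.

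Adamts19 transcripts were lower in every KO library than in any WT library. Adamts19 (ENSMUSG00000053441, mm10 chromosome 18, 58836667 to 59054060, plus strand, 23 exons in the longest coding transcript) lies between Isoc1 and Minar2. Its level over all cells was 39.9, 29.2, 50.0, 16.9, 31.6, 15.7 and 22.2 CPM in WT replicates 1 to 7. It was 6.25, 5.73, 8.68, 8.38, 7.14, 5.82, 5.29 and 5.62 CPM in KO replicates 1 to 8. The fall was -2.17 log2 (SE 0.21, n = 7 and 8, edgeR adjusted p = 4.25e-05), from 29.4 ± 12.5 to 6.61 ± 1.31 CPM. With flow cell as a covariate it was -2.27 (SE 0.34, adjusted p = 0.028). The tags come from the 3′ end, where the last exon (59052537 to 59054060) lies. The deleted part is not given in the sources used here, so these values check the labels only by the amount of the transcript's end.

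In WT hearts Adamts19 was highest in valve interstitial-like cells, the mesenchyme of the valve leaflets. These cells held 116 ± 32.2 CPM against 19.9 ± 9.52 in all other cells, a log2 difference of 2.55 ± 0.37 (SD) seen in 7 of 7 libraries (exact sign-flip p = 0.0156, the smallest possible). Cardiomyocyte-like cells held 28.2 ± 12.5 CPM and fibroblast-like cells 11.7 ± 5.59. Endocardial-like cells held 3.62 ± 4.45 CPM in WT, where WT replicate 3 alone held 13.0 and the others 0 to 4.06, and 0 UMIs in KO, which allows up to 0.455 CPM. Adamts19 fell by 1.65 log2 in valve interstitial-like cells (SE 0.17, adjusted p = 4.26e-06), from 116 ± 32.1 to 38.2 ± 7.42 CPM. In cardiomyocyte-like cells it fell by 2.39 (SE 0.23, adjusted p = 1.69e-05), from 28.2 ± 12.5 to 5.43 ± 1.84 CPM. With flow cell as a covariate the log2 changes in these classes were -1.85 (SE 0.30, adjusted p = 0.0173) and -1.81 (SE 0.43, adjusted p = 0.4).

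LacZ, the bacterial reporter gene carried by many targeted alleles, had UMIs in each KO library and 0 UMIs in the 7 WT libraries, which allows up to 0.0534 CPM. KO replicates 1 to 8 held 32.4, 42.7, 91.3, 5.4, 20.1, 18.8, 17.5 and 18 CPM of LacZ over all cells. In valve interstitial-like cells KO libraries held 85.6 ± 38.2 CPM (n = 8), in cardiomyocyte-like cells 38.9 ± 43.6, where KO replicate 3 alone held 136 and the others 5.98 to 63.7, and in endocardial-like cells 0.901 ± 1.15 (0 to 3.05). LacZ UMIs were seen in 12% of KO valve interstitial-like cells (95% interval 10.9 to 13.3) and in 0.178% of KO endocardial-like cells (0.0652 to 0.386), at median depths of 1370 and 1334 UMIs. After thinning to 1000 UMIs these shares were 7.9% and 0.0486%, from 1899 and 2058 cells. Whether the WT reads were counted against a reference with LacZ is not given in the sources used here.

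**Figure D1:**
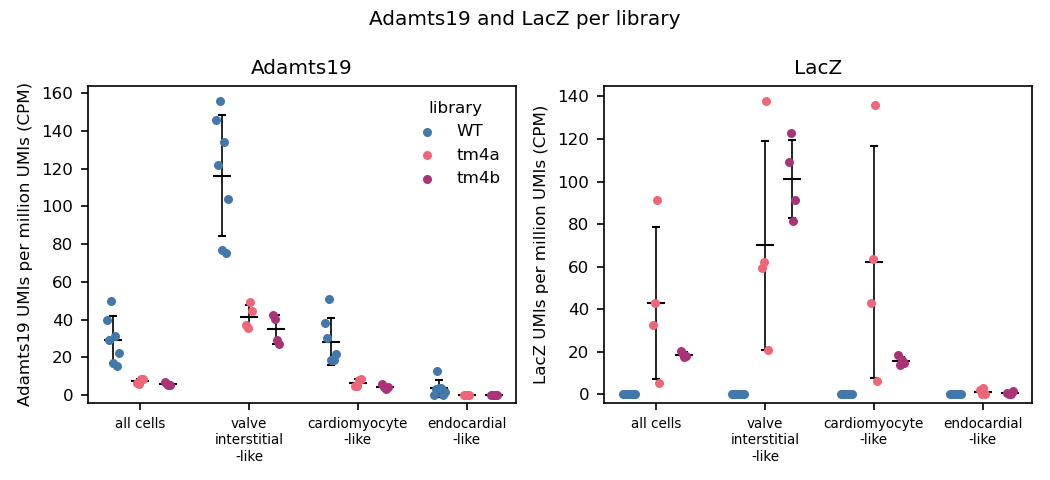
Adamts19 and LacZ in CPM (y axes) per library (points) for WT, tm4a and tm4b libraries, over all cells and in valve interstitial-like, cardiomyocyte-like and endocardial-like cells, with mean ± SD. Adamts19 over all cells lies between 15.7 and 50.0 CPM in WT and between 5.29 and 8.68 CPM in KO libraries, and LacZ lies at 0 in WT.

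The makeup of the hearts did not differ past the threshold in any of 9 classes after adjustment. Cardiomyocyte-like cells made up 41.7% ± 4.53 of WT and 43.3% ± 5.26 of KO cells (n = 7 and 8, exact permutation adjusted p = 0.681), and valve interstitial-like cells 11.3% ± 3.70 and 10.4% ± 1.55 (adjusted p = 0.691). Fibroblast-like cells made up 12.4% ± 2.05 and 14.1% ± 2.48 (exact permutation adjusted p = 0.391), endocardial-like cells 10.3% ± 2.85 and 11.9% ± 2.06 (0.416), vascular endothelial-like cells 2.58% ± 1.32 and 3.46% ± 0.989 (0.391), mural-like cells 4.49% ± 2.85 and 3.52% ± 2.1 (0.681) and macrophage-like cells 2.39% ± 0.685 and 2.44% ± 0.993 (0.913). Epicardial-like cells made up 2.57% ± 1.01 and 3.90% ± 1.04 (p = 0.0274, adjusted p = 0.123, exact permutation). Erythroid-like cells made up 1.95% ± 3.30 and 0.205% ± 0.129 (p = 0.00668, adjusted p = 0.0601, exact permutation), and WT replicate 4 alone held 9.34%. Without WT replicate 1 or 2 the erythroid-like difference passed (exact permutation adjusted p = 0.03 and 0.0239), and without WT replicate 4 the difference of -1.75 percentage points became -0.52 (0.126). Valve endothelial-like cells, added later, made up 3.29% ± 1.12 and 3.28% ± 0.382 (exact permutation p = 0.987). Dissociation and depth can set such shares, and within the KO flow cell there is only WT replicate 5.

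**Figure D2:**
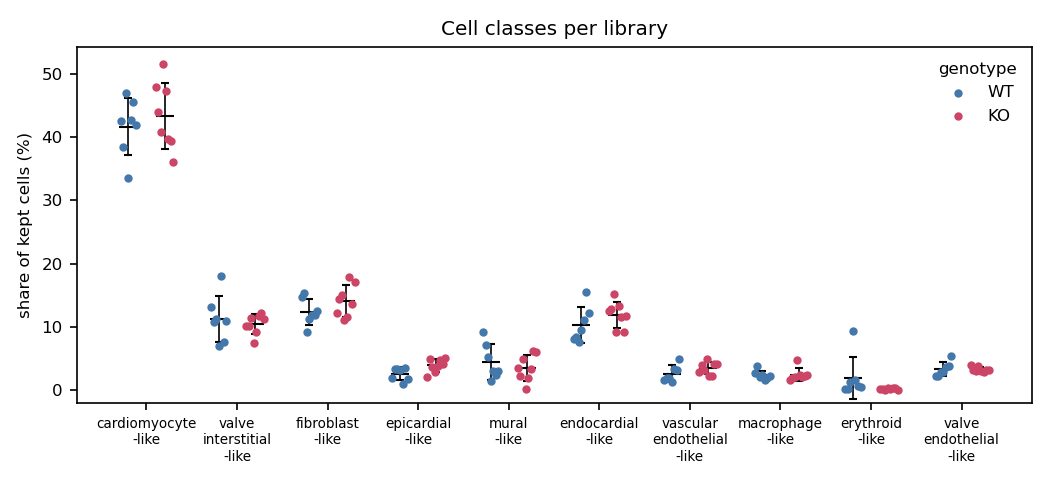
Percent of kept cells (y axis) per library (points) in 10 cell classes for WT (n = 7) and KO (n = 8) libraries. Erythroid-like cells of WT replicate 4 stand at 9.34%, and in no class did the groups differ past the adjusted threshold.

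Over all cells of the heart, Adamts19 had the largest fall of the 28 genes that separated KO from WT with edgeR. Pcna, the sliding clamp of DNA replication, rose by 0.72 log2 (SE 0.11, adjusted p = 0.0119, n = 7 and 8), from 144 ± 26.6 to 237 ± 21.5 CPM with no overlap between the groups. Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, rose by 0.82 (SE 0.17, adjusted p = 0.0477), and Tra2a, a splicing factor, by 0.66 (SE 0.12, adjusted p = 0.0382). Gja5, a connexin gene among those leading the trabecular-type cluster, fell by 0.67 (SE 0.14, adjusted p = 0.0468), from 45.8 ± 10.2 to 28.8 ± 3.85 CPM. The edgeR test called 28 of 13437 genes, 17 higher and 11 lower in KO. Further named genes rose by 0.45 to 0.76: Pcgf5 of the Polycomb group (0.76), the uncharacterised 5430416N02Rik (0.72), Tsr1 (0.60), Lpar6 (0.60), the homeobox gene Pknox1 (0.58), Bcr (0.57), Gpr116 (0.55), the small heat shock gene Hspb8 (0.53) and the sterol carrier Stard4 (0.45). Gm10076 (-1.46), Gm1673 (-0.75), Tpgs1 (-0.59) and Hint2 (-0.53) fell. Genes named Gm are predicted models, some of them near copies of other genes, so their counts are uncertain.

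With flow cell as a covariate 6 genes passed over all cells, 1 of the 28 (Adamts19) among them. The others, named after their values were seen, are Gal (-3.03), Rhd (-2.59), Igtp (-2.04), Col9a3 (-1.37) and Kif6. Pcna then stood at 0.67 (SE 0.19, adjusted p = 0.316) and Gja5 at 0.08 (SE 0.24, adjusted p = 0.956). When counts were summed per litter 2 genes passed, both among the 28 and Adamts19 one of them. The count of 28 was 414 without WT replicate 3, 97 without WT replicate 1, and 5 to 15 without any 1 of the other 13 libraries. Without WT replicates 1 to 4, a comparison chosen after the data were seen, 975 genes passed, 27 of the 28 among them, and DESeq2 called 466, with the 28 among them. Among the 18 named genes past the threshold, 3 (Adamts19, Pcna and 5430416N02Rik) passed in each fit that left out 1 library.

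Of the 23 gene lists, 5 passed over all cells at the preset correlation. Immediate early and heat shock genes lay higher (22 tested, median log2 fold change 0.26, adjusted p = 5.34e-05, or adjusted p = 0.811 with an estimated correlation), and adjusted over the list alone 5 rose. Nuclear-encoded oxidative phosphorylation genes lay lower (49 tested, median -0.16, adjusted p = 0.000127, or adjusted p = 0.98 with an estimated correlation), and adjusted over the list alone 1 fell. Haemoglobin genes lay lower (7 tested, median -1.51, adjusted p = 0.0022, or adjusted p = 0.811 with an estimated correlation), and adjusted over the list alone 7 fell. Haemoglobin took 1.56% ± 1.93 of UMIs in WT and 0.346% ± 0.151 in KO libraries, and WT replicate 4 alone held 5.77% where the other WT libraries held 0.19 to 1.69%. Shear stress response genes lay higher (15 tested, median 0.13, adjusted p = 0.0479, or adjusted p = 0.811 with an estimated correlation), and adjusted over the list alone 1 rose. Calcium handling and conduction genes lay lower (14 tested, median -0.14, adjusted p = 0.0491, or adjusted p = 0.811 with an estimated correlation), with Gja5 the 1 that fell, over all genes and adjusted over the list alone. With flow cell as a covariate the oxidative phosphorylation, immediate early and haemoglobin lists passed in camera at the preset correlation but not in fry. That fit was not run with an estimated correlation.

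The other 18 lists did not pass over all cells. For matrix genes the medians and adjusted p-values were -0.11 and 0.306 for the ADAMTS family without Adamts19, -0.05 and 0.999 for proteoglycans, 0.00 and 0.922 for collagens, -0.06 and 0.922 for basement membrane, and -0.24 and 0.0829 for elastic fibre. For genes near Adamts19 they were -0.19 and 0.398. For regulators they were 0.49 (median 0.06) for valve development transcription factors, 0.999 (0.07) for the Notch pathway, 0.306 (0.12) for the TGF-beta and BMP pathway and 0.748 (0.03) for the Wnt pathway. For growth and metabolism they were 0.118 (0.08) for DNA replication, 0.0834 (0.11) for mitosis, 0.972 (-0.06) for glycolysis and hypoxia, 0.1 (0.13) for mitochondrially encoded genes and 0.748 (-0.04) for cytosolic ribosomal proteins. They were 0.999 (-0.05) for interferon and MHC class I, 0.49 (-0.08) for abundant cardiomyocyte transcripts and 0.922 (0.56) for sex-linked genes. The test pointed upward against a negative median for proteoglycans and for glycolysis and hypoxia, and upward against a negative mean for collagens. Adjusted over the list alone, 3 DNA replication genes rose and 1 fell, 2 mitochondrially encoded genes rose, and 1 gene rose in each of the basement membrane, mitosis and glycolysis lists. In the lists of basement membrane and genes near Adamts19 1 fell, and the other lists had 0.

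Markers of other cell types moved over all cells beside these lists. Erythroid markers lay lower (12 tested, median -1.50, adjusted p = 8.03e-05, or adjusted p = 0.86 with an estimated correlation), and adjusted over the list alone 10 fell. Epicardial markers (11 tested, median 0.40, adjusted p = 0.0431, or adjusted p = 0.86 with an estimated correlation) and valve endothelial markers (9 tested, 0.23, adjusted p = 0.0431, or adjusted p = 0.412 with an estimated correlation) lay higher, and adjusted over the list alone 1 rose in each. The medians were -0.10 (adjusted p = 0.316) for cardiomyocyte, -0.01 (0.73) for valve interstitial, 0.02 (0.73) for fibroblast, -0.10 (0.465) for mural, 0.11 (0.73) for endocardial, 0.19 (0.0583) for vascular endothelial and 0.14 (0.73) for lymphatic endothelial markers. They were -0.04 (adjusted p = 0.825) for macrophage, -0.05 (0.764) for other leukocyte or platelet, 0.08 (0.73) for neural crest, glial or neuronal and -0.11 (0.416) for hepatocyte markers. Epithelial markers had under 3 tested genes.

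In valve interstitial-like cells, the class with most Adamts19 and the tissue of the valve disease, edgeR called 7 genes and DESeq2 87. Pcna rose by 0.82 log2 (SE 0.13, adjusted p = 0.00377, n = 7 and 8), from 148 ± 20.7 to 262 ± 42.0 CPM. The RNA-binding genes Tra2a and Tial1 rose by 0.80 (SE 0.16, adjusted p = 0.0467) and 0.61 (SE 0.12, adjusted p = 0.0422). Nppa, a peptide hormone made by cardiomyocytes, fell by 1.16 (SE 0.19, adjusted p = 0.00377), from 263 ± 69.8 to 117 ± 40.7 CPM, and Gm10076 fell by 1.64 (SE 0.27, adjusted p = 0.00377). With LacZ and Adamts19 these are the 7 genes called of 8593 by edgeR, 4 higher and 3 lower. The valve matrix and regulatory genes did not pass: Hapln1 stood at 0.33 (SE 0.20, adjusted p = 0.475), Postn at 0.18 (0.614), Vcan at 0.07 (0.852), Sox9 at 0.06 (0.915) and the flow-responsive Klf2 at -0.03 (0.976).

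By list, DNA replication genes lay higher in valve interstitial-like cells (20 tested, median 0.22, adjusted p = 0.00247, or adjusted p = 0.692 with an estimated correlation), where 1 rose and, adjusted over the list alone, 3. Immediate early and heat shock genes lay higher (22 tested, 0.43, adjusted p = 5.24e-07, or adjusted p = 0.692 with an estimated correlation), where adjusted over the list alone 6 rose. Oxidative phosphorylation genes lay lower (49 tested, -0.17, adjusted p = 1.63e-05, or adjusted p = 0.847 with an estimated correlation), where adjusted over the list alone 1 fell. Haemoglobin genes lay lower (6 tested, -1.08, adjusted p = 0.004, or adjusted p = 0.692 with an estimated correlation), where adjusted over the list alone 4 fell. Abundant cardiomyocyte transcripts lay lower (15 tested, -0.62, adjusted p = 1.95e-08, or adjusted p = 0.692 with an estimated correlation), where 1 fell and, adjusted over the list alone, 8. These 15 transcripts took 0.581% ± 0.11 of the class's UMIs in WT and 0.445% ± 0.11 in KO. With flow cell in the model 2 genes passed, Adamts19 and LacZ, and Pcna stood at 0.79 (adjusted p = 0.439), and with counts summed per litter 3 passed, Adamts19, LacZ and Gm10076. The edgeR count was 22 without the low-count filter, 16 with called doublets kept and 11 at Leiden resolution 1.5. In comparisons chosen after the data were seen it was 424 without WT replicates 1 to 4 (the 7 among them), 27 in the largest cluster alone and 23 without the 5% of highest doublet scores. The count of 7 was 92 without WT replicate 3, 16 without KO replicate 4, 12 without WT replicate 1, and 5 to 9 without any 1 of the other libraries.

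In endocardial-like cells, the inner lining of the heart, 25 genes changed, Jun, Rhob and Pcna among those that rose. Jun, an immediate early transcription factor, rose by 0.78 log2 (SE 0.17, adjusted p = 0.0474, n = 7 and 8), from 1142 ± 349 to 1962 ± 447 CPM, and Rhob, an early-response GTPase, by 1.31 (SE 0.22, adjusted p = 0.0109). Pcna rose by 0.75 (SE 0.16, adjusted p = 0.0414), Cdkn1c by 0.76, Tra2a by 0.82 and the phosphate transporter Slc20a1 by 0.97 (SE 0.17, adjusted p = 0.0112). The cardiomyocyte troponins Tnni3 and Tnni1 fell by 0.87 (adjusted p = 0.0417) and 0.65 (adjusted p = 0.0417). Of 8379 genes tested with edgeR, 14 were called higher and 11 lower. Of 20 named genes past the threshold, 4 passed in each fit that left out 1 library. The imprinted H19_1 (1.63), Hist1h2bc (1.02), Nfkbiz (0.97), Snhg9 (0.89), mt-Nd5 (0.81) and Zc3h7a (0.71) also rose, and Gm7808 (-1.68), Gm10076 (-1.60), Gm10269 (-1.36), Gm1673 (-0.77), the respiratory chain subunit Uqcrfs1 (-0.76) and Vti1b (-0.71) fell. Klf2 at 0.64 (SE 0.23, adjusted p = 0.207), Hapln1 at 0.28 (0.548), Postn at 0.03 (0.948) and Vcan at -0.10 (0.889) did not pass, and Sox9 was below the count filter.

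Immediate early and heat shock genes lay higher as a group in endocardial-like cells (22 tested, median 0.46, adjusted p = 2.07e-07, or adjusted p = 0.359 with an estimated correlation), where 1 rose and, adjusted over the list alone, 10. DNA replication (20 tested, 0.26, adjusted p = 0.000566, or adjusted p = 0.546 with an estimated correlation) and mitochondrially encoded genes (9 tested, 0.35, adjusted p = 0.000566, or adjusted p = 0.313 with an estimated correlation) lay higher, where 1 of each rose and, adjusted over the list alone, 3 of each. Mitosis genes lay higher (21 tested, 0.16, adjusted p = 0.0183, or adjusted p = 0.678 with an estimated correlation), where adjusted over the list alone 0 passed. Oxidative phosphorylation genes lay lower (48 tested, -0.25, adjusted p = 2.9e-10, or adjusted p = 0.515 with an estimated correlation), where adjusted over the list alone 9 fell. Ribosomal protein genes lay lower (75 tested, -0.16, adjusted p = 0.000537, or adjusted p = 0.68 with an estimated correlation), where adjusted over the list alone 2 fell. Abundant cardiomyocyte transcripts lay lower (15 tested, -0.69, adjusted p = 4.89e-12, or adjusted p = 0.313 with an estimated correlation), where 2 fell and, adjusted over the list alone, 11. They took 0.472% ± 0.12 of UMIs in WT and 0.316% ± 0.091 in KO. Cluster 12, led by Plvap and the heat shock gene Hspa1b, held 25.3% of WT and 35.1% of KO endocardial-like cells, pooled over libraries and not tested. It is the shallowest endocardial-like cluster, at a median of 610.5 UMIs against 2248 and 1926 in clusters 4 and 21. KO cells of the class were also shallower (median 1334 against 1753 UMIs in WT), so these shares cannot be told apart from depth. With flow cell in the model 7 genes passed, 0 of the 25 among them, and Jun stood at 1.26 (adjusted p = 0.305), and with counts summed per litter edgeR called 0 genes (684 at an unadjusted p under 0.05). The count of 25 was 159 without WT replicate 3, 69 without WT replicate 1, 44 without KO replicate 1, and 5 to 16 without any 1 of WT replicates 4 to 7 or KO replicates 2, 5, 7 and 8.

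In valve endothelial-like cells, the Hapln1- and Edn1-rich cells covering the leaflets, the 3 genes called, each coding for a mitochondrial protein, were lower in KO. Cox5a, a subunit of cytochrome c oxidase, fell by 1.07 log2 (SE 0.16, adjusted p = 0.00109, n = 7 and 8), from 480 ± 91.8 to 226 ± 45.3 CPM. Cyc1 of the respiratory chain fell by 0.77 (SE 0.15, adjusted p = 0.0229) and the mitochondrial dehydrogenase Idh2 by 0.73 (SE 0.14, adjusted p = 0.0229), and these were the genes called of 4684. Of genes that did not pass, Pcna stood at 0.66 (adjusted p = 0.0902), Hspa1b at 1.83 (0.0937), Mafg at 1.00 (0.0937), Tra2a at 0.70 (0.096), Tmem64 at 0.93 (0.112), Myl3 at -1.48 (0.0581) and Cox5b at -0.67 (0.0581). Oxidative phosphorylation genes lay lower (46 tested, median -0.25, adjusted p = 1.41e-11, or adjusted p = 0.256 with an estimated correlation), where 1 fell and, adjusted over the list alone, 10. Shear stress response genes lay higher (14 tested, 0.21, adjusted p = 0.00385, or adjusted p = 0.199 with an estimated correlation), where adjusted over the list alone 0 passed. Immediate early and heat shock genes lay higher (22 tested, 0.15, adjusted p = 0.0386, or adjusted p = 0.75 with an estimated correlation) and haemoglobin genes lower (5 tested, -0.89, adjusted p = 0.0149, or adjusted p = 0.56 with an estimated correlation). Adjusted over the list alone 3 immediate early genes rose and 1 fell, and 5 haemoglobin genes fell. Abundant cardiomyocyte transcripts lay lower (15 tested, -0.81, adjusted p = 1.27e-13, or adjusted p = 0.199 with an estimated correlation), where adjusted over the list alone 13 fell, and took 0.576% ± 0.26 of UMIs in WT and 0.312% ± 0.061 in KO. With flow cell in the model edgeR called 0 genes (351 at an unadjusted p under 0.05), and 0 with counts summed per litter (466 unadjusted). The count of 3 was 28 without WT replicate 3, 12 without WT replicate 7, 9 without WT replicate 1, 7 without KO replicate 1, 5 without WT replicate 4 and 1 without WT replicate 5 or KO replicate 2, 5 or 7.

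In vascular endothelial-like cells edgeR called 0 of 4106 genes (396 at an unadjusted p under 0.05, and 4 by DESeq2). The genes with the smallest p-values in each direction did not pass. Kif23, a motor of cytokinesis, stood at 0.83 log2 (SE 0.15, edgeR adjusted p = 0.0578, n = 7 and 8), Incenp at 0.67 (0.344), Pcna at 0.61 (0.303), Bzw2 at 0.59 (0.303) and Tmem64 at 1.38 (0.303). Gm10076 stood at -1.34 (0.344), Rnpep at -0.93 (0.344), Tm9sf2 at -0.86 (0.344), Pfdn2 at -0.75 (0.303) and Mrpl14 at -0.65 (0.344). Mitosis genes lay higher as a group (21 tested, median 0.29, adjusted p = 0.0062, or adjusted p = 0.884 with an estimated correlation), and elastic fibre genes lower (6 tested, -0.37, adjusted p = 0.0105, or adjusted p = 0.587 with an estimated correlation). Oxidative phosphorylation genes (47 tested, -0.17) and abundant cardiomyocyte transcripts (15 tested, -0.52) lay lower (adjusted p = 6.75e-05 for each, or adjusted p = 0.884 for each with an estimated correlation). Adjusted over the list alone 0 members of these 4 lists passed. Once flow cell was included 1 gene passed (Mgp at -3.07, named after its value was seen), and without WT replicate 3 edgeR called 3 genes, and 1 without KO replicate 3 or 4.

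In cardiomyocyte-like cells 174 genes changed, with Ddit4 and Atf3 among those that rose and Fbln5, Lum and Col1a1 among those that fell, and markers of fibroblasts, valve interstitial cells and endocardium lay lower beside them. Ddit4, a stress-induced inhibitor of mTOR, rose by 1.12 log2 (SE 0.20, adjusted p = 0.012, n = 7 and 8), from 19.6 ± 5.78 to 43.1 ± 13.1 CPM, and Atf3, a stress-induced transcription factor, by 0.92 (SE 0.15, adjusted p = 0.0118), from 209 ± 51.9 to 396 ± 79.4. The elastic fibre gene Fbln5 fell by 1.5 (SE 0.32, adjusted p = 0.024), the proteoglycan Lum by 1.10 and the fibrillar collagen Col1a1 by 1.09 (SE 0.23, adjusted p = 0.024), from 52.6 ± 24.4 to 24.9 ± 7.58 CPM. Gja5 fell by 0.65 (SE 0.13, adjusted p = 0.0159). Of 11271 genes tested with edgeR, 101 were called higher and 73 lower. Bcr (0.93), Nr4a1 (0.88), 5430416N02Rik (0.87), Tmem64 (0.85), Gem (0.79), Pcgf5 (0.79), the cholesterol synthesis gene Hsd17b7 (0.75), the endoplasmic reticulum stress factor Ddit3 (0.74), Dot1l (0.73) and Ier3 (0.73) also rose. Gm10076 (-1.43), Gm1673 (-0.76), H2afj (-0.76), Pgls (-0.75), Agrn (-0.73), Zfp428 (-0.69), Akr7a5 (-0.68), Apoe (-0.67), Ppp3r1 (-0.59) and Tpgs1 (-0.57) fell.

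Collagens and collagen processing genes lay lower in cardiomyocyte-like cells (22 tested, median -0.27, adjusted p = 0.000337, or adjusted p = 0.389 with an estimated correlation), where 3 fell (Col1a1, Col6a1 and Loxl1) and, adjusted over the list alone, 9 fell and 1 rose. Elastic fibre genes lay lower (12 tested, -0.42, adjusted p = 2.1e-05, or adjusted p = 0.276 with an estimated correlation), where 3 fell (Fbln5, Fbln2 and Fbn1) and, adjusted over the list alone, 7. Proteoglycans lay lower (11 tested, -0.21, adjusted p = 0.023, or adjusted p = 0.389 with an estimated correlation), where 2 fell (Lum and Bgn) and, adjusted over the list alone, 3. Markers of fibroblasts (11 tested, -0.38, adjusted p = 0.00211, or adjusted p = 0.355 with an estimated correlation), valve interstitial cells (10 tested, -0.28, adjusted p = 0.0243, or adjusted p = 0.355 with an estimated correlation) and endocardium (10 tested, -0.42, adjusted p = 0.00176, or adjusted p = 0.305 with an estimated correlation) lay lower beside them. Immediate early and heat shock genes (22 tested, 0.20, adjusted p = 0.000337, or adjusted p = 0.389 with an estimated correlation) and mitosis genes (21 tested, 0.15, adjusted p = 0.00264, or adjusted p = 0.481 with an estimated correlation) lay higher. Of the former 3 rose (Atf3, Ier3 and Nr4a1) and, adjusted over the list alone, 4, and of the latter, adjusted over the list alone, 1. Oxidative phosphorylation (49 tested, -0.13, adjusted p = 0.000664, or adjusted p = 0.882 with an estimated correlation) and haemoglobin genes (6 tested, -0.81, adjusted p = 0.0395, or adjusted p = 0.718 with an estimated correlation) lay lower, where adjusted over the list alone 1 and 6 fell.

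In lists that did not pass in cardiomyocyte-like cells, Adamts1 (0.62), Pcna (0.72), Mcm2 (0.46) and mt-Nd5 (0.66) rose, and Notch1 (-0.99) and the secreted Wnt inhibitor Sfrp2 (-1.30) fell. The abundant cardiomyocyte transcripts took 10.6% ± 0.98 of UMIs in WT and 10.7% ± 0.46 in KO cardiomyocyte-like cells. The trabecular-type cluster held 9.6% of the WT and 6.0% of the KO cells of this class. Once flow cell was included 2 genes passed, 0 of the 174 among them (Gal at -3.61 and Ifitm3 at -2.44, named after their values were seen), and Ddit4 stood at 1.02 (adjusted p = 0.593), Col1a1 at -1.0 (0.62) and Gja5 at 0.01 (0.994). With counts summed per litter, not taking littermates as independent, 2 genes passed, Adamts19 one of them, and 172 of the 174 did not. The count of 174 was 469 without WT replicate 3 and 71 to 113 without any 1 of WT replicates 2, 5, 6 and 7 or KO replicates 4 to 8. Of 38 named genes past the threshold 18 passed in each fit that left out 1 library.

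In fibroblast-like cells, the Tcf21-rich cells of the myocardial wall, the cardiomyocyte genes Nppa, Mybpc3 and Tnni1 were among 9 genes that fell. Nppa fell by 1.16 log2 (SE 0.18, adjusted p = 0.0117, n = 7 and 8), from 267 ± 69.7 to 119 ± 33.6 CPM. The sarcomere genes Mybpc3 and Tnni1 fell by 1.28 (SE 0.22, adjusted p = 0.0226) and 0.99 (SE 0.17, adjusted p = 0.0174). Pcna rose by 0.68 (SE 0.13, adjusted p = 0.0444), Tra2a by 0.68 and the collagen hydroxylase Leprel2 by 0.94 (SE 0.19, adjusted p = 0.0445). The edgeR test called 15 of 9037 genes, 6 higher and 9 lower, among them Tmem64 (0.99), Tsr1 (0.71) and 5430416N02Rik (0.69) higher and Gm10076 (-1.50), Gm8730 (-1.24), H2afj (-0.95), Hint2 (-0.69) and Gm1673 (-0.69) lower. Abundant cardiomyocyte transcripts lay lower (15 tested, median -0.72, adjusted p = 1.74e-10, or adjusted p = 0.386 with an estimated correlation), where 2 fell and, adjusted over the list alone, 13, and they took 0.541% ± 0.11 of UMIs in WT and 0.405% ± 0.071 in KO. Oxidative phosphorylation (49 tested, -0.18, adjusted p = 3.71e-05, or adjusted p = 0.585 with an estimated correlation), calcium handling (5 tested, -0.49, adjusted p = 0.0383, or adjusted p = 0.367 with an estimated correlation) and haemoglobin genes (6 tested, -1.19, adjusted p = 9.82e-05, or adjusted p = 0.493 with an estimated correlation) lay lower, where adjusted over the list alone 3, 1 and 6 fell. Mitochondrially encoded genes lay higher (9 tested, 0.17, adjusted p = 0.0408, or adjusted p = 0.493 with an estimated correlation), where adjusted over the list alone 2 rose. Once flow cell was included 4 genes passed, 1 of the 15 (Gm8730, -2.19, adjusted p = 0.0206) and, named after their values were seen, Mt1 (-2.19), Myh7 (-1.99) and Myl3 (-1.64), and Nppa stood at -1.53 (adjusted p = 0.139), and with counts summed per litter 1 gene passed, not one of the 15. The count of 15 was 31, 14, 111, 5, 0, 4 and 17 without WT replicates 1 to 7. It was 3, 1, 15, 7, 3, 2, 1 and 1 without KO replicates 1 to 8. Of 14 named genes 0 passed in every fit.

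A few genes passed in several classes. Pcna and Tra2a rose, and Gm10076 fell, in 4 classes each (valve interstitial-, endocardial-, cardiomyocyte- and fibroblast-like), and Gm1673 fell in 3. The log2 fold change of Pcna lay between 0.61 and 0.82 and that of Gm10076 between -1.64 and -1.31 in the 6 classes tested. These classes come from the same libraries, so they are not independent of one another.

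**Figure D3:**
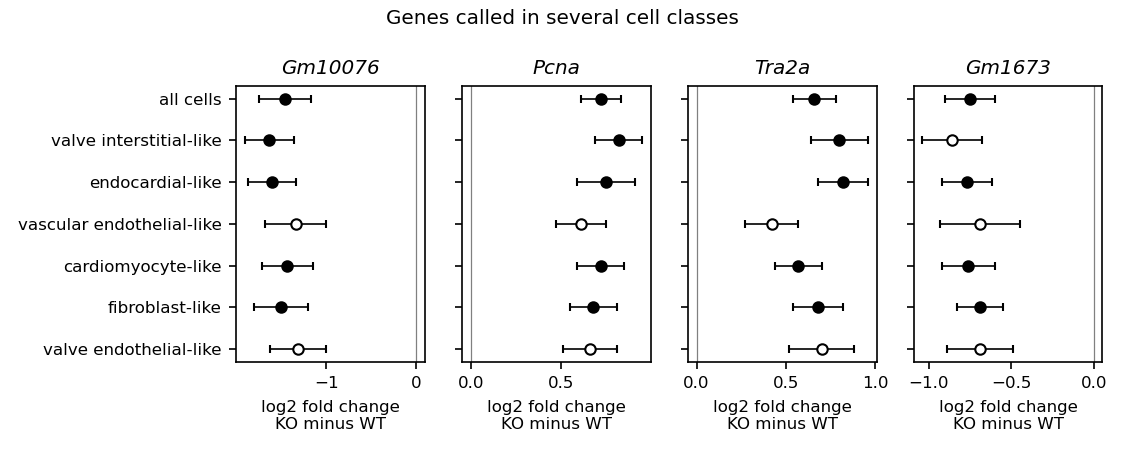
Log2 fold change of KO over WT (x axis, with SE) for Gm10076, Pcna, Tra2a and Gm1673 over all cells and in each class, filled where the adjusted p is under 0.05. Pcna lies between 0.61 and 0.82 and Gm10076 between -1.64 and -1.31 in the 6 classes.

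Among KO hearts, many genes separated the tm4b from the tm4a libraries. In the usual naming of targeted alleles, an allele ending in b is derived from the one ending in a by removal of a part of it. Tbx18, a transcription factor of the epicardium, rose by 1.03 log2 in tm4b (SE 0.09, adjusted p = 0.000755, n = 4 and 4), from 28.7 ± 2.90 to 58.4 ± 2.61 CPM, and Sfrp2, a secreted Wnt modulator, by 1.42 (SE 0.31, adjusted p = 0.0128). The glycolytic genes Pgk1 and Aldoa fell by 1.34 (SE 0.31, adjusted p = 0.0159) and 0.89 (SE 0.10, adjusted p = 0.00147), and the ribosomal protein gene Rps18 by 0.88 (SE 0.08, adjusted p = 0.000755). Adamts19 stood at -0.37 (SE 0.19, adjusted p = 0.219). The edgeR test called 2082 of 13527 genes, 1075 higher and 1007 lower in tm4b. H19_1 (1.25), Lox (1.18), Srsf9 (1.07), Antxr1 (1.05), Smoc2 (1.04), Gm26771 (1.00), Ints8 (0.98), Ndst1 (0.89), Tnc (0.87) and Pkd2 (0.84) also rose. Hmgn2 (-1.23), Eno1 (-1.21), Rps7 (-1.14), Ndufs5 (-1.13), Rpl35 (-1.05), Rpl36 (-0.99), Mrps21 (-0.96), Nts (-0.96), Rpl41 (-0.95), Tomm5 (-0.94) and Hmgb1 (-0.93) fell. The tm4a libraries come from litters 5 and 6 and the tm4b libraries from litter 7, so allele and litter cannot be told apart.

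By list, oxidative phosphorylation genes lay lower in tm4b (49 tested, median -0.46, adjusted p = 2.55e-19, or adjusted p = 0.448 with an estimated correlation), where 39 fell and, adjusted over the list alone, 47. Ribosomal protein genes lay lower (78 tested, -0.32, adjusted p = 1.78e-08, or adjusted p = 0.465 with an estimated correlation), where 27 fell and 2 rose and, adjusted over the list alone, 37 fell and 2 rose. Glycolysis and hypoxia genes lay lower (23 tested, -0.51, adjusted p = 3.29e-08, or adjusted p = 0.35 with an estimated correlation), where 14 fell and, adjusted over the list alone, 15. DNA replication (20 tested, -0.15, adjusted p = 0.00722, or adjusted p = 0.465 with an estimated correlation) and mitosis genes (21 tested, -0.17, adjusted p = 0.00641, or adjusted p = 0.465 with an estimated correlation) lay lower, where 4 and 6 fell, Aurka (-0.62) and Fen1 (-0.49) among them, and adjusted over the list alone 7 of each. Wnt pathway (21 tested, 0.46, adjusted p = 0.00109, or adjusted p = 0.35 with an estimated correlation) and TGF-beta and BMP pathway genes (26 tested, 0.24, adjusted p = 0.00307, or adjusted p = 0.35 with an estimated correlation) lay higher. In each of these 6 rose, with Fzd7 (1.11), Wnt5a (0.73), Bmp2 (0.71) and Smad1 (0.62) among them, and adjusted over the list alone 7 of each. The ADAMTS family without Adamts19 lay higher (20 tested, 0.30, adjusted p = 0.00415, or adjusted p = 0.465 with an estimated correlation), where 3 rose (Adamts2, Adamts5 and Adamts12) and, adjusted over the list alone, 4.

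At the preset correlation 12 of the 23 lists passed, and 0 with an estimated one (3 at an unadjusted p under 0.05, and 5 past the threshold by fry). Genes near Adamts19 lay higher in tm4b (5 tested, median 0.41, adjusted p = 0.031, or adjusted p = 0.448 with an estimated correlation), where Isoc1 (0.57) and Slc12a2 (0.41) rose and, adjusted over the list alone, 4. Elastic fibre genes lay higher (16 tested, 0.33, adjusted p = 0.0375, or adjusted p = 0.58 with an estimated correlation), where Ltbp3 (0.56) and Fbn1 (0.41) rose and, adjusted over the list alone, 3. Mitochondrially encoded genes lay lower (9 tested, -0.26, adjusted p = 0.0309, or adjusted p = 0.465 with an estimated correlation), where 3 fell and, adjusted over the list alone, 3. Abundant cardiomyocyte transcripts lay lower (15 tested, -0.39, adjusted p = 7.13e-05, or adjusted p = 0.465 with an estimated correlation), where 5 fell and, adjusted over the list alone, 10. In lists that did not pass, the valve regulators Sox9 (0.67), Foxc1 (0.63) and Zeb2 (0.57), the hyaluronan synthase Has2 (0.80) and the collagen Col11a1 (0.78) rose. The heat shock gene Hspa8 (-0.57) and the channel subunit Kcne1 (-0.61) fell. The median transcript length was 4811 bases for genes higher and 1833 for genes lower in tm4b, against 3372 for genes not called. The count of 2082 was 771 without KO replicate 7, 1073 without KO replicate 8 and 1240 without KO replicate 6.

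In valve interstitial-like cells, 308 of 8458 genes separated tm4b from tm4a, 163 higher and 145 lower in tm4b. Foxc1, a regulator of valve mesenchyme, rose by 1.53 log2 (SE 0.23, adjusted p = 0.00341, n = 4 and 4), from 30.5 ± 9.05 to 84.7 ± 16.3 CPM, and the matrix glycoprotein Tnc by 0.91 (SE 0.14, adjusted p = 0.0033). Rps18 fell by 1.10 (SE 0.11, adjusted p = 6.74e-05), from 1336 ± 75.4 to 624 ± 32.0 CPM, and Rpl35 by 1.38 (SE 0.18, adjusted p = 0.00133). Hspb1 (1.47), Kcnj15 (1.38), Zfp251 (1.24), Rprd2 (1.21), Sfrp2 (1.18), Hist1h1c (1.16), Ipo8 (1.15), Alyref (1.14), 1110065P20Rik (1.14), Zfhx4 (1.13) and Micu2 (1.13) also rose. Btf3 (-1.45), Hmgn2 (-1.44), Cdkn1a (-1.31), Ttn (-1.28), Eno1 (-1.27), H2-Ab1 (-1.25), Cdk2ap2 (-1.15), Baiap2 (-1.04), Rpl36 (-1.02) and Rpl41 (-1.02) fell. Adamts19 (-0.28, adjusted p = 0.512), Sox9 (0.64, 0.081), Hapln1 (-0.57, 0.108), Postn (-0.34, 0.118), Vcan (0.13, 0.58) and Klf2 (-0.02, 0.985) did not pass. Wnt pathway genes lay higher (16 tested, 0.29, adjusted p = 0.0178, or adjusted p = 0.246 with an estimated correlation), where 5 rose and, adjusted over the list alone, 6, and ribosomal protein genes lower (75 tested, -0.33, adjusted p = 7.52e-11, or adjusted p = 0.405 with an estimated correlation), where 23 fell and, adjusted over the list alone, 33. TGF-beta and BMP pathway genes lay higher (21 tested, 0.43, adjusted p = 0.00109, or adjusted p = 0.246 with an estimated correlation), where 2 rose and, adjusted over the list alone, 5. At the preset correlation 11 of the 23 lists passed, and 0 with an estimated one (3 at an unadjusted p under 0.05, and 3 past the threshold by fry). The count of 308 was 157, 69, 64, 43 and 88 without KO replicates 1, 3, 5, 7 and 8.

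In endocardial-like cells 54 of 8543 genes separated the alleles, 28 higher and 26 lower in tm4b. H19_1, an imprinted noncoding RNA, rose by 1.63 log2 (SE 0.20, adjusted p = 0.00108, n = 4 and 4), from 66.6 ± 26 to 217 ± 26.6 CPM, and Aldoa fell by 0.84 (SE 0.12, adjusted p = 0.00629), from 384 ± 21.4 to 214 ± 15.9. Rps18 fell by 0.83 (SE 0.12, adjusted p = 0.00629) and the early-response gene Zfp36 by 1.03 (SE 0.21, adjusted p = 0.0361). Cep135 (1.36), Ints8 (1.31), Prex2 (1.20), Ngly1 (1.10), Prkrir (1.00), Srsf9 (1.00), Zbtb1 (0.95), Ndst1 (0.95), Serpine2 (0.91), Cab39 (0.84) and Erbb2ip (0.83) also rose. Nhp2l1 (-1.03), Supt4a (-0.96), Tmsb10 (-0.94), Mrps21 (-0.91), Psap (-0.90), Gng5 (-0.87), mt-Co1 (-0.86), Hmgb1 (-0.85) and Mrpl55 (-0.83) fell. Vcan (0.40, adjusted p = 0.349), Klf2 (-0.17, 0.826), Postn (-0.14, 0.693) and Hapln1 (0.04, 0.957) did not pass. Glycolysis and hypoxia genes lay lower (17 tested, -0.45, adjusted p = 2.17e-06, and adjusted p = 0.036 with an estimated correlation), where 1 fell and, adjusted over the list alone, 8. Immediate early and heat shock genes lay lower (22 tested, -0.48, adjusted p = 2.17e-06, or adjusted p = 0.769 with an estimated correlation), where 2 fell and, adjusted over the list alone, 10. At the preset correlation 5 of the 23 lists passed, and 1 with an estimated one. The count of 54 was 37, 11, 11, 107, 28, 5, 1 and 16 without KO replicates 1 to 8. Of 27 named genes 1 (H19_1) passed in every fit.

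LacZ UMIs were spread differently over the cell classes in tm4a and tm4b libraries before adjustment, and the adjusted p missed the threshold. In tm4a libraries 71.9% ± 6.68 of LacZ UMIs came from cardiomyocyte-like and 15.5% ± 6.16 from valve interstitial-like cells. In tm4b libraries these shares were 39.7% ± 6.68 and 48.8% ± 5.07 (n = 4 and 4, exact permutation p = 0.0286 for each, the smallest possible, adjusted p = 0.0667 over 7 tests). The log2 ratio of LacZ CPM in cardiomyocyte-like to valve interstitial-like cells was -0.56 ± 0.85 in tm4a and -2.69 ± 0.35 in tm4b libraries (exact permutation p = 0.0286, adjusted p = 0.0667). LacZ over all cells was 42.9 ± 35.9 and 18.6 ± 1.13 CPM (exact permutation p = 0.2), in valve interstitial-like cells 70.0 ± 49.1 and 101 ± 18.5, and in cardiomyocyte-like cells 62.2 ± 54.7 (136 in KO replicate 3) and 15.6 ± 2.05. Adamts19 was 7.26 ± 1.49 and 5.97 ± 0.812 CPM (exact permutation p = 0.2). Here too allele and litter cannot be told apart.

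**Figure D4:**
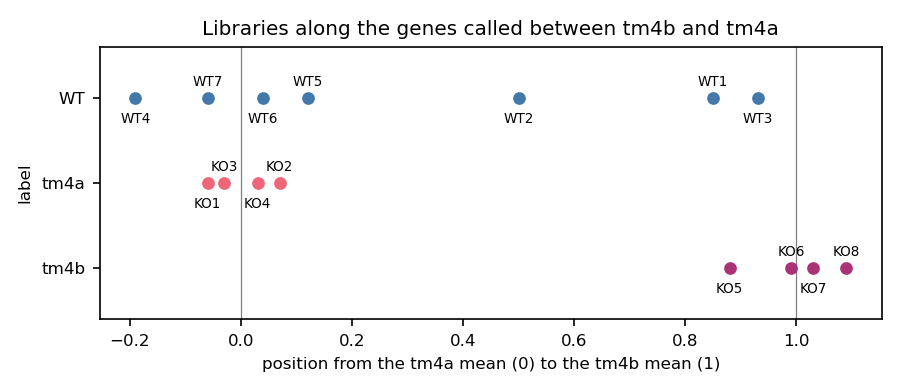
Position of each library (points) on a scale from the tm4a mean (0) to the tm4b mean (1) over the 2082 genes called between these alleles, for WT, tm4a and tm4b libraries. WT libraries, which carry neither allele, lie between -0.19 and 0.93. The genes were chosen for separating tm4b from tm4a libraries, so these lie apart by construction.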

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

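The tests of the allele alone, of fewer cardiomyocytes and of LacZ, those in valve endothelial-like cells, those without WT replicates 1 to 4, the removal of the 5% of cells with the highest doublet scores and the counts over other splits of the libraries were chosen only after the results were seen.

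More genes separated tm4b from tm4a libraries, by a direct test of that difference, than KO from WT: 2082 against 28 over all cells, 308 against 7 in valve interstitial-like and 54 against 25 in endocardial-like cells. In endocardial-like cells the order turned with DESeq2 (107 against 118), without the 5% of highest doublet scores (49 against 52), without WT replicate 1 (54 against 69) or 3 (54 against 159) and without KO replicate 1 (37 against 44), 3 (11 against 20), 6 (5 against 21) or 7 (1 against 5), and without WT replicates 1 to 4 it turned there (54 against 521) and in valve interstitial-like cells (308 against 424). A changed cell makeup is argued against, since the median change in valve interstitial-like cells was 1.01 times that over all cells, and so is litter 6 standing alone, since KO replicate 1 of litter 5 lay 0.15 of the way from litter 6 to litter 7 over 1488 genes called without it. The WT libraries cannot decide whether the allele is the only source. They carry neither allele yet spread over 1.11 of the distance between the alleles, which does not test what separates the KO libraries. The widest spread within an allele was 0.21, but the genes were chosen for separating the alleles, which favours a small spread within each. The ends of the WT spread, WT replicates 3 (0.93) and 4 (-0.19), share a litter and a flow cell, so position is not set by litter or flow cell alone in that pair. Transcript length may account for a part, since the log2 change rose with length (Spearman rho = 0.37). Limma called 1932 genes before and 933 after that trend was removed, 817 in both, so length is argued against as the whole cause. Allele, litter and library handling stay open and untested, since all tm4b libraries are littermates (litter 7).

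Abundant cardiomyocyte transcripts lay lower in KO outside cardiomyocyte-like cells (median log2 fold change -0.62 in valve interstitial-like, -0.69 in endocardial-like and -0.72 in fibroblast-like cells) and stood at -0.02 in cardiomyocyte-like cells. Doublets with cardiomyocytes among the cells of high doublet score are argued against, since without the 5% of cells with the highest scores the fall in fibroblast-like cells was 1.14 times as large, though the score recognised few doublets. Fewer cardiomyocytes in the KO suspensions cannot be told apart from other causes, since the share of these cells was 1.65 percentage points higher in KO, which lies within its spread (41.7% ± 4.53 in WT and 43.3% ± 5.26 in KO, exact permutation p = 0.53). Nor can less free cardiomyocyte RNA in KO libraries, since the median was -0.18 in macrophage-like, -0.41 in mural-like and -0.49 in epicardial-like cells, and the 15 transcripts ranged from -0.90 to 0.45 in macrophage-like cells. An effect of the genotype stays open and untested, and the flow cell is confounded with it.

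LacZ UMIs lay in other cell classes in tm4b than in tm4a libraries, with a log2 ratio of cardiomyocyte-like to valve interstitial-like cells that differed by -2.13. Free LacZ RNA is argued against, since the level in endocardial-like cells of tm4a libraries was 0.0239 of that in cardiomyocyte-like cells. A different share of the classes is argued against, since the ratio is taken per UMI of each class and the libraries did not overlap (-3.18 to -2.35 in tm4b, -1.79 to 0.04 in tm4a), at the smallest exact permutation p that 4 against 4 libraries can give (p = 0.0286), though the adjusted p of 0.0667 misses the threshold. Litter 7 cannot be told apart from the allele, since 0 tm4b libraries come from a litter other than 7. The allele itself, which the design names, stays open and untested for the same reason.

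The splits of the libraries below treat littermates as independent, although no litter holds both genotypes or both alleles, so they speak only of chance among single libraries and leave chance differences between litters open. Of 100 splits of the 15 libraries into 7 and 8, only the real one called as many genes in cardiomyocyte-like cells (174, highest other 4). In endocardial-like cells the real split alone did so too (25 genes, 1 of 100, highest other 4). This argues against such chance in these classes but does not exclude it, since only 100 splits were drawn. Other splits can also break up litters, which the real one keeps whole. Few splits called as many genes in valve interstitial-like cells (7 genes, 2 of 100, highest other 19) and fibroblast-like cells (15 genes, 2 of 100, highest other 839). The same held for valve endothelial-like cells (3 genes, 4 of 100, highest other 28) and all cells (28 genes, 3 of 100, highest other 1217). In these sums some other splits called more genes than the real one, so such chance is not excluded there either. Adamts19 and LacZ, which the knockout itself sets, are among the 7 genes in valve interstitial-like cells, and Adamts19 is among the 28. With sums per litter, edgeR called 2 genes in cardiomyocyte-like, 0 in endocardial-like (684 at an unadjusted p under 0.05), 3 in valve interstitial-like, 1 in fibroblast-like and 0 in valve endothelial-like cells (466 unadjusted), and 2 over all cells. In vascular endothelial-like cells edgeR called 0 genes (396 at an unadjusted p under 0.05, 4 by DESeq2), 100 of 100 splits gave as many, the highest 22, and chance cannot be excluded. The split that called 1217 genes set WT replicates 4, 5 and 7 with KO replicates 1 to 4 against the rest, and the split that called 839 set WT replicates 2 and 4 to 7 with KO replicates 2 and 3 against the rest. Counts that many times the real one point to a structure among the libraries other than genotype, and WT replicates 4 to 7 lie with the tm4a libraries on the scale between the alleles (-0.19 to 0.12). Between the alleles, 1 of 35 splits, the real one, gave as many genes. That held over all cells (2082, highest other 6), in valve interstitial-like (308, 8) and in endocardial-like cells (54, 17). It argues against chance among single libraries, but with 1 litter of tm4b chance between litters stays open.

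Single libraries lay far from the rest of their group in 41 of 602 groups tested, where about 1 in 20 groups would do so by chance. The value of the library is given first, and the range of the rest of its group in parentheses. Erythroid-like cells made up 9.34% of WT replicate 4 (0.16 to 1.64) and macrophage-like cells 4.80% of KO replicate 4 (1.58 to 2.43). In WT replicate 3 these were, in CPM, H19_1 at 96.05 (27.4 to 57.0) and Cdkn1c at 6112 (2754 to 3610) in endocardial-like cells, Dot1l at 144 (59.2 to 92.6) in cardiomyocyte-like cells, and Tmem64 at 107 (0 to 43.4) in vascular endothelial-like, 49.0 (15.3 to 26.5) in cardiomyocyte-like and 250.2 (65.0 to 117) in valve endothelial-like cells. In WT replicate 4, Gm10076 stood at 709 (79.9 to 345.5) in vascular endothelial-like, 377 (69.7 to 194) in cardiomyocyte-like and 582 (102 to 309) in fibroblast-like cells. In WT replicate 1, Klf2 stood at 697 (277 to 458) in endocardial-like and Myl3 at 1274 (188 to 624.8) in valve endothelial-like cells, and in WT replicate 7, 5430416N02Rik at 14.54 (23.03 to 28.7) in cardiomyocyte-like cells.

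Among the 8 KO libraries, Gpr116 stood at 85.8 CPM in KO replicate 5 (63.0 to 72.7) and Gja5 at 37.6 in KO replicate 2 (25.6 to 29.2) over all cells. In KO replicate 6, Vcan stood at 2227 (1481 to 1771) in valve interstitial-like, Pfdn2 at 48.05 (124.5 to 153) in vascular endothelial-like and Pcna at 266 (170 to 209) in cardiomyocyte-like cells. In KO replicate 3, Gm7808 stood at 52.4 (8.16 to 25.4) in endocardial-like, 5430416N02Rik at 76.0 (36.1 to 44.7) and Ddit3 at 167 (99.6 to 120) in cardiomyocyte-like, and Gm10076 at 178 (54.6 to 104) in fibroblast-like cells. In KO replicate 4, Mybpc3 stood at 57.7 (16.9 to 31.1) and Gm1673 at 128 (85.1 to 104.5) in fibroblast-like cells.

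Among the 4 libraries of an allele, over all cells, KO replicate 5 held Eno1 at 108 CPM (57.3 to 64.2), Rps7 at 54.1 (25.8 to 30.2), Col14a1 at 83.5 (98.7 to 101) and Tgfbr3 at 51.5 (42.35 to 43.65). KO replicate 3 held Ccnb1 at 74.6 (95.1 to 96.9) and Rps18 at 1220 (1176 to 1180), and KO replicate 2 held mt-Nd4 at 1861 (2123 to 2143). In valve interstitial-like cells, KO replicate 4 held Ttn at 532 (130 to 139), Cdk2ap2 at 75.6 (37.9 to 38.4) and Atp5j at 491 (417 to 429), and KO replicate 2 held Sox9 at 415 (216 to 239) and Tnc at 185 (145 to 149). There KO replicate 5 held Rpl41 at 1297 (844 to 910), KO replicate 6 Fzd1 at 64.9 (104 to 106) and Fzd7 at 43.7 (65.1 to 68.75), and KO replicate 7 Cdkn1a at 165 (53.2 to 68.6).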

How the results depend on the processing

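The tests without the 5% of cells with the highest doublet scores, in the largest valve interstitial-like cluster alone, in valve endothelial-like cells and without WT replicates 1 to 4 were chosen only after the results were seen, and the cause of the shifts below was not tested. The values are numbers of genes past the threshold in edgeR unless said otherwise, for KO against WT over all cells and in valve interstitial-, endocardial-, vascular endothelial-, cardiomyocyte-, fibroblast- and valve endothelial-like cells, in this order, where the report gives 28, 7, 25, 0, 174, 15 and 3. DESeq2 called 466, 87, 118, 4, 413, 127 and 31. With flow cell as a covariate, where genotype rests on WT replicate 5 alone, the counts were 6, 2, 7, 1, 2, 4 and 0 (351 at an unadjusted p under 0.05 for the last). With a block for the replicate number they were 2, 2, 0 (634 unadjusted), 0 (254), 3, 3 and 1, but the numbers do not pair the samples, since no WT library resembled the KO library of its own number most (r from -0.56 to 0.20 over 5202 genes). With sums per litter they were 2, 3, 0 (684 unadjusted), 0 (303), 2, 1 and 0 (466). Without WT replicates 1 to 4 they were 975, 424, 521, 15, 886, 245 and 44, of which 27, 7, 21, 0, 126, 13 and 2 were shared with the report's counts. Without the low-count filter 22 genes passed in valve interstitial-like, 73 in endocardial-like, 5 in vascular endothelial-like, 29 in fibroblast-like and 47 in valve endothelial-like cells, and between the alleles 479 in valve interstitial-like and 179 in endocardial-like cells, where DESeq2 called 107. With called doublets kept 16 passed in valve interstitial-like and 1 in valve endothelial-like cells. Without the 5% of highest doublet scores 23 passed in valve interstitial-like, 52 in endocardial-like and 2 in vascular endothelial-like cells. At Leiden resolution 1.5 the count in valve interstitial-like cells was 11, in the largest of their clusters alone 27, and with at least 500 genes per cell that in fibroblast-like cells 8. The tm4a libraries alone against WT gave 2 genes over all cells and the tm4b libraries alone 20. Leaving out 1 library at a time gave 5 to 414 genes over all cells, 5 to 92 in valve interstitial-like, 5 to 159 in endocardial-like, 0 to 3 in vascular endothelial-like, 71 to 469 in cardiomyocyte-like, 0 to 111 in fibroblast-like and 1 to 28 in valve endothelial-like cells. Each of these highest counts came without WT replicate 3. Between the alleles it gave 771 to 2203 genes over all cells, 43 to 317 in valve interstitial-like and 1 to 107 in endocardial-like cells. The difference in the erythroid-like share ranged from -2.05 to -0.52 percentage points.

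Of single genes, Gja5 changed direction with flow cell as a covariate, at 0.081 over all cells (adjusted p = 0.956) and 0.009 in cardiomyocyte-like cells (adjusted p = 0.994). Of the 99 values of named genes past the threshold between KO and WT, not counting Adamts19 over all cells, which kept it in each of these fits, 94 lost it with that covariate beside the 2 of Gja5, 91 lost it with the replicate block and 95 with litter sums, and under DESeq2 9 others gained it. The number of gene lists past the threshold, in the order above 5, 5, 7, 4, 7, 5 and 5, became 0 in each case with an estimated correlation in camera, where 0, 0, 2, 1, 2, 2 and 3 lists had an unadjusted p under 0.05 and fry passed 0, 0, 0, 0, 1, 1 and 0. Once flow cell was a covariate it was 9 in valve interstitial-like and 10 in fibroblast-like cells. Depth limits what can be seen in the smaller classes: KO endocardial-like cells held 0 Adamts19 UMIs, which allows up to 0.455 CPM.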

Other observations

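All tests and comparisons in this part were chosen only after the values were seen. Within the cell classes, Adamts19 in WT hearts, in CPM pooled over libraries, stood at 156 in the larger valve interstitial-like cluster. It stood at 66.2 in the mitotic cluster of that name, whose class is less certain, and at 72.2 in the trabecular-type cluster, where single WT libraries ran from 17.8 to 111. The 3 cardiomyocyte-like clusters 7, 10 and 17 held 39.4, 43.4 and 39.1 CPM, and the 3 endocardial-like clusters 2.85 to 5.86. In tm4a hearts LacZ stood at 155, 96.1 and 87.3 CPM in cardiomyocyte-like clusters 7, 10 and 17, 85.2 in the larger valve interstitial-like cluster and 73.9 in the trabecular-type cluster. In tm4b hearts it stood at 28.8, 22.1 and 22.6 in clusters 7, 10 and 17, 125 in the larger valve interstitial-like cluster, 48.6 in that mitotic cluster and 44.8 in the trabecular-type cluster. These levels pool libraries of unequal level (LacZ over all cells ran from 5.4 to 91.3 CPM in tm4a), so they give no order of the clusters, they were not tested against one another, and allele and litter cannot be told apart.

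The tm4b and tm4a hearts were also compared within further classes. Between the alleles edgeR called 1421 genes in cardiomyocyte-like, 957 in fibroblast-like, 172 in epicardial-like, 80 in vascular endothelial-like, 63 in mural-like and 19 in valve endothelial-like cells, and 0 in macrophage-like cells (353 at an unadjusted p under 0.05).

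WT replicates 1 to 4 also differed from WT replicates 5 to 7, with 45 genes past the threshold over all cells (4 higher and 41 lower in replicates 1 to 4), 69 in valve interstitial-like, 65 in endocardial-like, 27 in vascular endothelial-like, 31 in cardiomyocyte-like, 51 in fibroblast-like and 24 in valve endothelial-like cells (edgeR, n = 4 and 3). WT replicate 5, the only WT library on the flow cell of the KO libraries, was placed between the mean of the other WT libraries (0) and the KO mean (1) over genes called without it, leaving out Adamts19 and LacZ. Its median position was 0.20 over 75 genes in cardiomyocyte-like cells, with 64 nearer WT and 11 nearer KO. In endocardial-like cells it was 0.20 over 12 genes, with 8 nearer WT, and over all cells -0.02 over 5 genes, with 4 nearer WT. This is 1 library, so it does not separate flow cell from genotype.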
